A study of Drosophila melanogaster with 4 samples.

How the data were processed

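Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Drosophila melanogaster third-instar larvae that carried a genomic Abd-B transgene with GFP in place of the stop codon. Abd-B is a homeodomain transcription factor of the bithorax complex. Per the labels, the antibody was a rabbit polyclonal against GFP, and 2 libraries of immunoprecipitated DNA and 2 libraries of input DNA were made. Per the labels' protocols, wandering larvae were collected and the chromatin was cross-linked with formaldehyde. The protocol text names another fly stock (y; bw cn sp) than the Abd-B-GFP strain given for all 4 samples, and the sample characteristics were followed here. No value used here checks that the larvae carried the tagged protein. Because the tissue is a whole larva, a peak averages over the chromatin of all its cells, whether or not the protein was bound in them.

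The deposited data used here were 1 peak list for the whole series, in GFF3 format. Per the file headers, its coordinates are on FlyBase release 5 (BDGP5), and its source column names MACS. CASAVA 1.7.0.2 and 1.7.0.3, BWA and MACS2 are named per the submitters' processing notes, without versions for BWA and MACS2. The threshold of the peak call, the filters on reads and the way in which the 2 ChIP and 2 input libraries were combined are not given in the sources used here. Each peak has a start, an end and 1 score. The score is the peak caller's own value, as the authors deposited it, and describes the peak, not a library. The file does not define the score. The deposited scores behave as −log10 of a Poisson p-value, as judged from the values: with a background rate of 66.43 per position, 881 of 4389 scores equalled, to 2 decimals, −log10 of the probability of more than a whole number of fragments. Chance coincidence would give 2.88% of the scores, and rates more than 0.1 away from the best one, between 2 and 300 in steps of 0.01, gave at most 330. Rates within 0.1 of the best share many of its matches and were left out of that comparison. A score of this kind rises with depth as well as with enrichment. No read counts per library were used here, so the depth per library is unknown. Intervals below cover counting error between peaks only, and no value has a replicate error. No column holds the values of a single sample.

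Peaks were counted per chromosome arm with exact Clopper-Pearson 95% intervals on shares. No genome or annotation of release 5 was used here. The gene table at hand is on release 6, and its coordinates were not combined with the peaks. The planned tests of peak positions relative to genes, of gene lists and of sequence motifs were therefore not run, and peaks are given by position only. In place of arm lengths, the span from the first to the last peak of each arm was used, with exact Poisson 95% intervals on peaks per Mb. Arms were compared through counts in bins of 1 Mb with two-sided permutation tests (100000 resamples) and Benjamini-Hochberg adjustment over the 10 pairs of major arms. The last, partial bin of each arm was left out. Bins are not biological replicates. The median score of chromosome 4 was compared with that of all 3915 runs of 40 neighbouring peaks on the major arms. These runs overlap.

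Clustering was measured as the median gap between neighbouring peaks and as the number of windows of a 50 kb grid that held 5 or more peaks, called crowded below. A peak belonged to the window of its midpoint. Both measures were set against 1000 random placements of the same peaks, without overlap, within the span of each arm (a placement permutation test). The smallest two-sided p these can give is 0.002. Placement was uniform over the span and took no account of where reads can be mapped or where regulatory DNA lies. A small p therefore tells only that the peaks were not placed uniformly, and not why. On simulated data of 4110 peaks, with 100 placements each, 3 of 40 random lists had p below 0.05 for the gaps and 2 for the windows, and all 10 clustered lists had it for both. The random lists came from the same uniform placement as the test, and the clustered lists were strongly grouped. This checks the calculation only, and not the effect of uneven mapping or of weaker grouping. For the score, 3 simulated background rates were recovered with an error that rounded to 0, and scores without steps gave a best rate only 1.04 times above the best of the rates more than 0.1 away.

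The rule for what is named was set before the data were examined: the 10 peaks with the highest score and the 5 windows of 50 kb with the most peaks. Alternatives set at the same time were a stricter list (the peaks at or above the median score, 2195 peaks), the major arms 2L, 2R, 3L, 3R and X alone, windows of 20 kb, and peaks less than 1 kb apart merged first. The span-based densities, the comparisons through bins, the runs of neighbouring peaks and the match of scores to Poisson tails were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.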

Results

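Binding of the Abd-B-GFP fusion protein was mapped in third-instar larvae labelled as 1 transgenic strain, from 2 libraries of GFP immunoprecipitated DNA and 2 libraries of input DNA. The design sets input libraries beside the immunoprecipitate, and the result used here is 1 list of 4389 peaks. How the input entered the peak call is not given in the sources used here. The peaks covered 2.32 Mb in all. Their median width was 411 bp, with quartiles at 288 and 658 bp and a range from 201 to 3726 bp. Their median score was 15.46, with quartiles at 11.06 and 28.21 and a range from 6.18 to 264.05. A score above 100 was reached by 140 peaks (3.19%). The list holds no separate values for the 2 ChIP libraries, so agreement between them could not be measured.

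The scores were not spread evenly over their range. Of the 4389 scores, 881 (20.1%, exact 95% interval 18.9 to 21.3%) equalled −log10 of a Poisson tail of a whole count at a single background rate of 66.43. Chance coincidence would give 2.88%. Scores that missed a tail by 0.01 were not counted, such as the 22 at 9.44 beside the tail at 9.45. Counting them would give 1131 scores (25.8%), against 8.63% by chance. The exact matches peaks are called below peaks scored against the genome-wide background. MACS takes the larger of a genome-wide and a local background, so the remaining peaks include those with a local background above the genome-wide one.

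**Figure D1:**
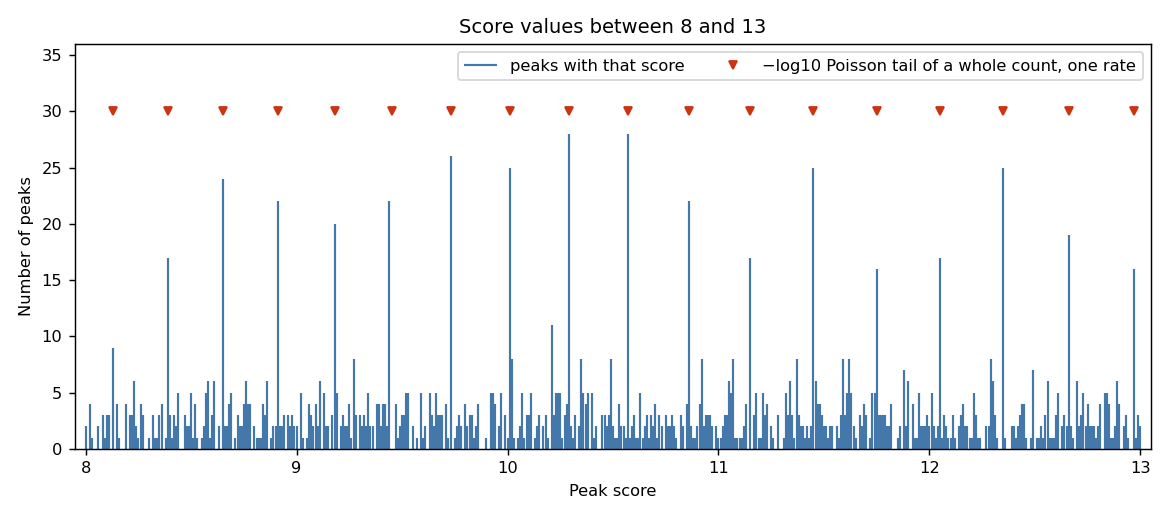
Number of peaks (vertical axis) at each score value with 2 decimals between 8 and 13 (horizontal axis, −log10 p). Triangles mark −log10 of the Poisson tails of successive whole counts at a rate of 66.43, and most of the tallest columns, with up to 28 peaks, stand below them. The 22 peaks at 9.44 stand 0.01 below the mark at 9.45, which holds 0.

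Peaks were found on every major arm. 3R, the arm that carries the bithorax complex with Abd-B itself, held the most, with 1048 peaks (23.9%, exact 95% interval 22.6 to 25.2%). 2R held 916 (20.9%, 19.7 to 22.1%), 3L held 833 (19.0%, 17.8 to 20.2%), X held 672 (15.3%, 14.3 to 16.4%) and 2L held 641 (14.6%, 13.6 to 15.7%). The small chromosome 4 held 40 peaks (0.911%, 0.652 to 1.24%). The remaining 239 peaks lay on unplaced, heterochromatic or mitochondrial sequence.

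Relative to the span between its first and last peak, 2R was the most densely bound arm, with 43.7 peaks per Mb (exact Poisson 95% interval 40.9 to 46.6). 2L was the least dense, with 28.0 peaks per Mb (25.9 to 30.3). 3R had 37.6 (35.3 to 39.9), 3L had 34.1 (31.8 to 36.5), chromosome 4 had 31.2 (22.3 to 42.4) and X had 30.2 (27.9 to 32.5). These Poisson intervals take peaks as independent, so the grouping of peaks described below makes them too narrow. In bins of 1 Mb, 2R had 43.6 ± 13.7 peaks (SD over 21 bins) and 2L had 28.3 ± 9.54 (SD over 22 bins), and these means differed (two-sided permutation test, adjusted p = 0.0016). The test treats bins as exchangeable, although neighbouring bins of an arm may not be independent. 2R also exceeded X, which had 30.5 ± 15.7 peaks per bin over 22 bins (adjusted p = 0.0266, permutation test). 3R, with 37.1 ± 14.0 peaks per bin over 27 bins, exceeded 2L (adjusted p = 0.0463, permutation test). For the other 7 pairs of arms the means did not differ at 0.05, with adjusted p from 0.0539 to 0.623 (permutation test). The bins of X ranged from 10 to 90 peaks.

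**Figure D2:**
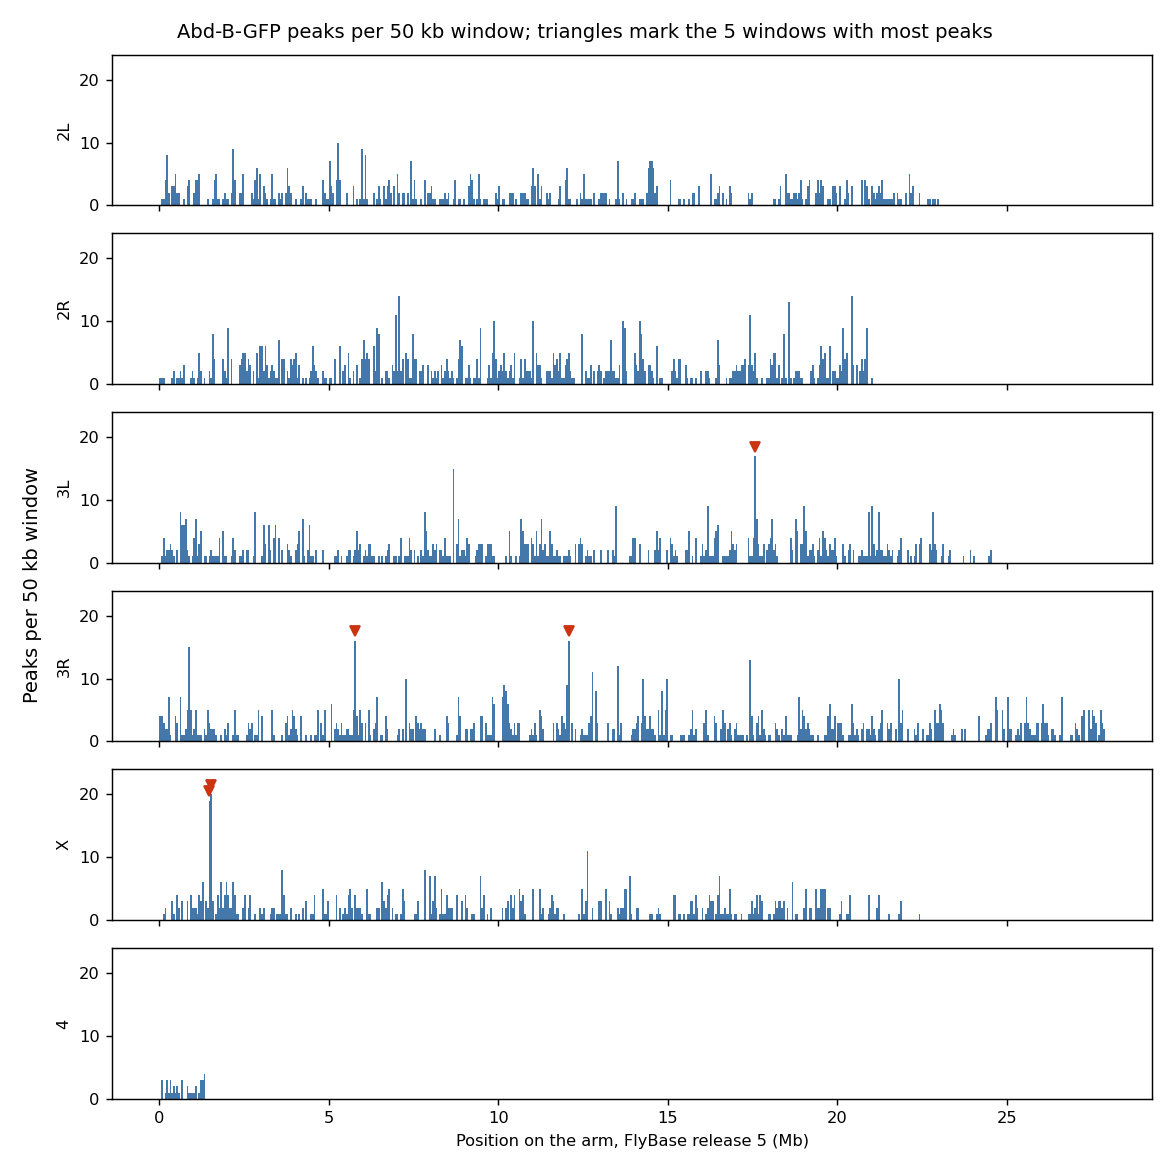
Number of Abd-B-GFP peaks (vertical axis) in each 50 kb window along 2L, 2R, 3L, 3R, X and chromosome 4 (horizontal axis, Mb in FlyBase release 5). Triangles mark the 5 windows with the most peaks, of which 2 adjoin near the low end of X with 19 and 20 peaks.

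Peaks on chromosome 4 and on X had higher scores than those on the large autosome arms. The median score was 26.43 on chromosome 4 and 16.98 on X, against 15.39 on 2L, 14.50 on 2R, 14.81 on 3L and 14.19 on 3R. A score above 100 was reached by 7 of 40 peaks on chromosome 4 (17.5%, exact 95% interval 7.34 to 32.8%) and by 34 of 672 on X (5.06%, 3.53 to 7.0%). On the autosome arms together it was reached by 86 of 3438 peaks (2.50%, 2.01 to 3.08%). The median score per 1 Mb bin was 18.36 ± 4.68 on X (SD over 22 bins) and 15.48 ± 2.97 on the autosome arms (SD over 94 bins), a difference of 2.88 (two-sided permutation test, p = 8e-04). Of all 3915 runs of 40 neighbouring peaks on the major arms, 34 had a median as high as that of chromosome 4 (exact over these runs, two-sided p = 0.0179). Among the 2195 peaks with a score of at least 15.46, neither comparison passed the threshold. There the X difference was 2.69 (permutation p = 0.1), and chromosome 4 stood at percentile 69.3 of the runs (rank among the runs, p = 0.614). That list is cut on the score being compared, which can by itself narrow such differences, so it does not decide whether they hold.

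**Figure D3:**
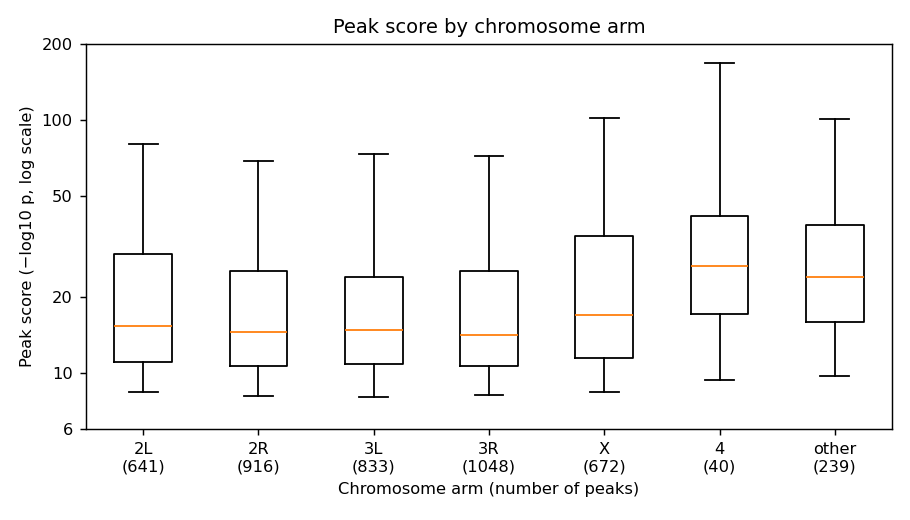
Peak score (vertical axis, −log10 p on a log scale) for each arm and for all other sequence, with the number of peaks below each name. Boxes span the quartiles, lines mark the medians and whiskers reach the 5th and 95th percentiles; the medians of chromosome 4 (26.43) and other sequence (24.02) lie above those of the major arms.

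The 10 strongest peaks were spread over 6 arms, with 3 on 3R, 3 on X and 1 each on 2L, 2R, 3L and chromosome 4. The strongest lay on 2R at 15993538 to 15994456, was 919 bp wide and had a score of 264.05. It was followed by a peak on 3R at 8889555 to 8890386 with a score of 254.32. On X, the peak at 19530929 to 19532461 had a score of 250.40, the one at 17720329 to 17721666 had 237.60 and the one at 2051829 to 2053306 had 225.67. The peak on 2L at 6323731 to 6324828 had a score of 233.41 and stood 14129 bp from its nearest neighbour. The peak on 3L at 16044965 to 16046293 had a score of 224.48 and was the most isolated of the 10, at 24471 bp. A further peak on 3R, at 27283501 to 27284884, had a score of 217.06. The strongest peak of chromosome 4, at 1316175 to 1317102, had a score of 214.33. The third of the 3R peaks, at 12758120 to 12760885, had a score of 210.10 and was the widest of the 10, at 2766 bp. It lay in the most crowded surroundings of the 10, in a 50 kb window with 11 peaks, whereas the other 9 lay in windows with 2 to 5. Which genes these positions fall in was not analysed here.

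Peaks were more grouped along the chromosomes than uniform random placement gives. The median gap between neighbouring peaks was 11299 bp, against 20630 bp in 1000 random placements (95% range 19997 to 21261 bp, two-sided placement permutation p = 0.002, the smallest they can give). Windows of 50 kb with 5 or more peaks numbered 231, against a mean of 75.5 and a maximum of 99 in the random placements (two-sided placement permutation p = 0.002, the smallest possible). They held 1568 peaks, or 35.7% of the list. 3R had 64 of these crowded windows, 2R had 57, 3L had 44, X had 35, 2L had 30, 3LHet had 1 and chromosome 4 had 0. Gaps under 1 kb made up 17.5% of all gaps, and merging across them left 3622 regions. Windows with 5 or more of these regions numbered 116, against 33.1 in random placements (two-sided placement permutation p = 0.002).

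**Figure D4:**
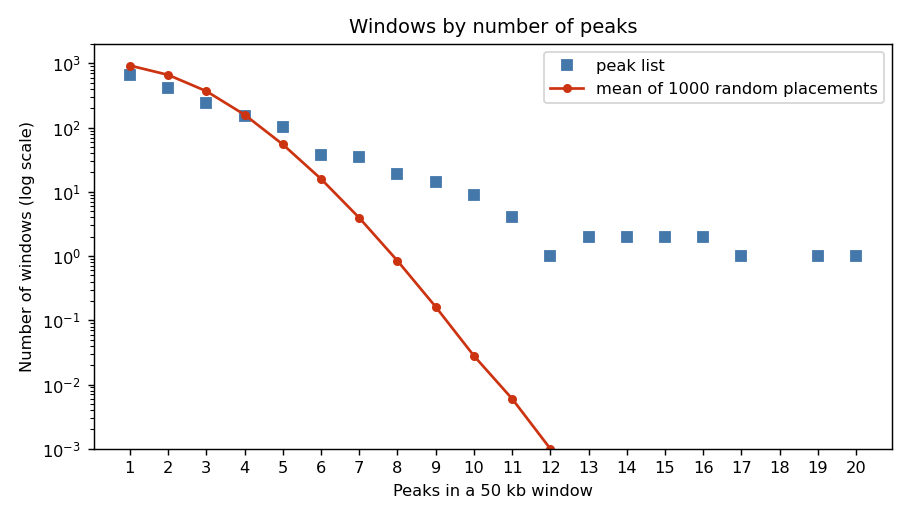
Number of 50 kb windows (vertical axis, log scale) by the number of peaks they hold (horizontal axis). Squares give the peak list and circles the mean of 1000 random placements; 25 windows of the list hold 10 or more peaks.

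The 2 windows with the most peaks adjoined each other on X. The window from 1500001 to 1550000 held 20 peaks that covered 28.4% of it, and the adjoining window from 1450001 to 1500000 held 19 that covered 24.5%. Scores in the first ran from 8.13 to 72.27 with a median of 13.17, and in the second from 6.84 to 75.69 with a median of 12.22. The widest peak of the whole list, 3726 bp at 1504034 to 1507759 with a score of 61.79, lay in the first. On 3L, the window from 17550001 to 17600000 held 17 peaks and 6 of them had scores above 50, up to 104.29 at 17562957 to 17563813. On 3R, the window from 12050001 to 12100000 held 16 peaks with a median score of 23.93, the highest median of the 5 windows. The other 3R window, from 5750001 to 5800000, also held 16 peaks, but its scores reached no more than 28.30. In 3 of the 5 windows (the one on 3L and both on 3R) 0 peaks were scored against the genome-wide background, though 1 in the first 3R window missed a tail by 0.01. The 2 X windows had 1 of 20 and 8 of 19 such peaks.

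**Figure D5:**
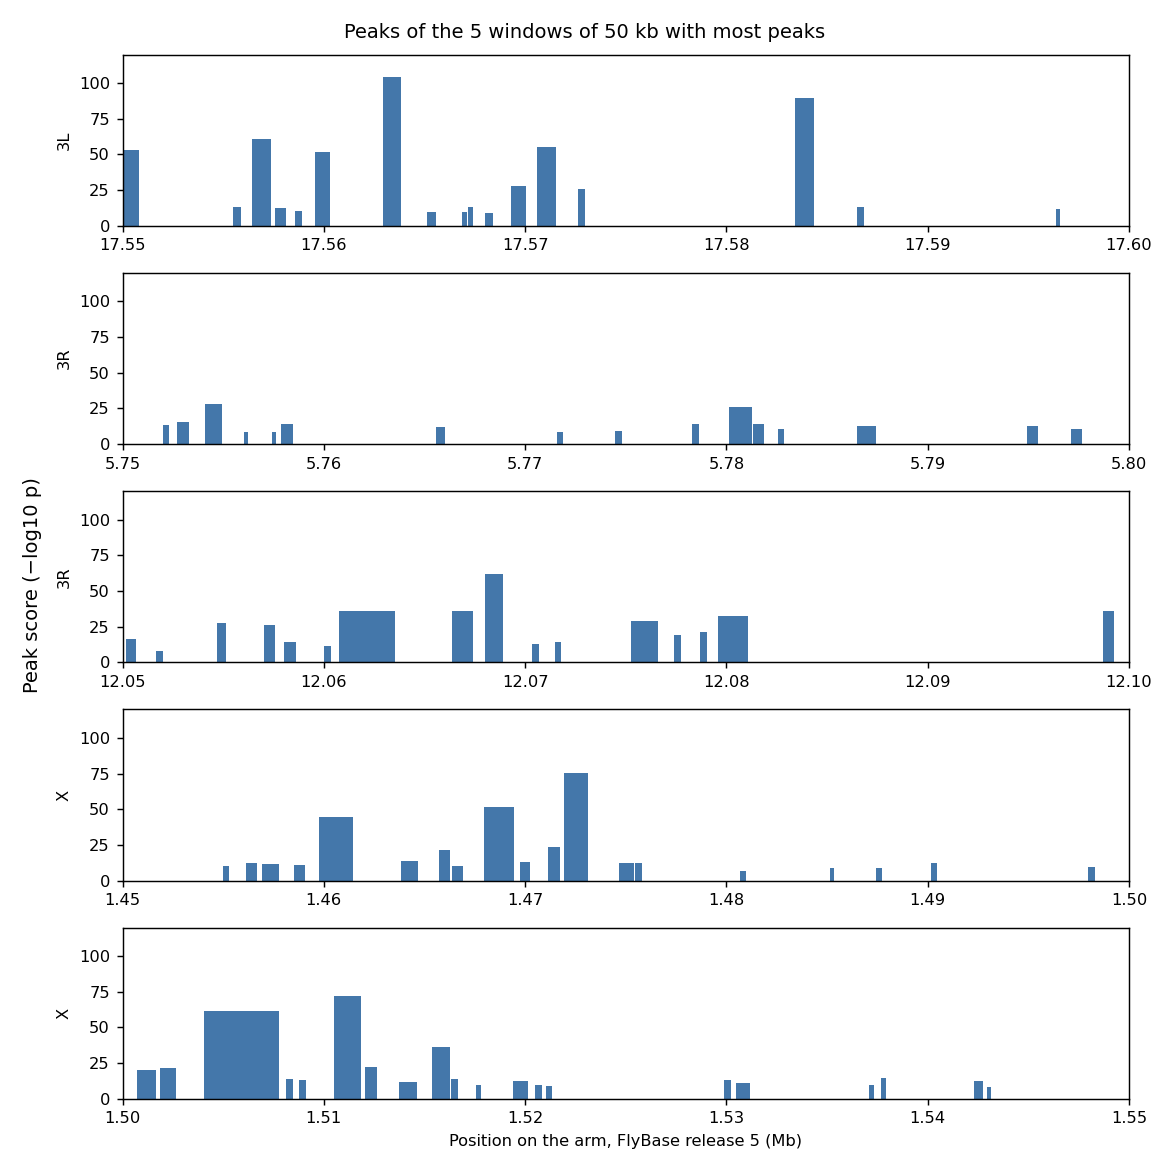
Peaks of the 5 windows of 50 kb with the most peaks, each drawn at its position (horizontal axis, Mb in FlyBase release 5) with its width to scale and its score as height (vertical axis, −log10 p). The 3L window reaches the highest score, 104.29, and the X window from 1500001 has the widest peak.

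Stronger peaks were wider. Across all 4389 peaks, score and width had a Spearman correlation of 0.733 (permutation p = 1e-05, the smallest that 100000 resamples can give). Peaks are not independent replicates, and a caller that extends a peak while its signal stays above a limit ties both measures together. In the fifth of the peaks with the lowest scores the median width was 259 bp, and in the fifth with the highest it was 820 bp. Of the 32 peaks wider than 2000 bp, 31 lay on the major arms.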

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

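The tests in this part were chosen after the results they bear on had been seen, except the merging of peaks less than 1 kb apart, which was set before the data were examined. Signal appeared on sequence that the comparisons between arms leave out: 187 peaks on the unplaced scaffolds U and Uextra, 50 peaks on heterochromatic scaffolds and 2 peaks on the mitochondrial genome. The mitochondrial peaks lay at 13864 to 14071 with a score of 15.64 and at 18919 to 19165 with a score of 34.86. The 239 peaks together made up 5.45% of the list, and their median score of 24.02 was above the 15.02 of the major arms. A locally raised input background at repeated sequence would lower the share of peaks scored against the genome-wide background. That share was instead 15.8 percentage points higher than on the major arms (35.1% against 19.3%, 95% bootstrap interval of the difference 9.64 to 21.9). It was 50.0% on the heterochromatic scaffolds and 31.0% on U and Uextra. The sets also differ in crowding, since all but 1 crowded window lay on the major arms. In major-arm windows with 1 or 2 peaks the mean share was 31.0 ± 43.3%. The share thus gives no sign of a raised input at these peaks, but the comparison does not separate it from their sparser placement. Reads that map to near-identical copies remain an open explanation, since read placements were not used here. No biological explanation was tested, because the design has no group that separates one.

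A second pattern is the crowding of peaks into 50 kb windows. Wide bound regions that the peak caller divided at gaps under 1 kb are argued against as its whole cause. Merging across such gaps lowered the crowded windows from 231 to 116. These were still 3.51 times as many as in random placements (two-sided placement permutation p = 0.002, the smallest the placements can give). Regions divided at wider gaps were not tested. A local background taken from the ChIP reads themselves was examined only in strong peaks. Of the 140 peaks with a score above 100, 20.7% were scored against the genome-wide background (exact 95% interval 14.3 to 28.4%), where chance coincidence gives 1.38%. This argues against such a background among these strong peaks. It does not address the crowding, because the peaks were not chosen from crowded windows. A locally raised input background in crowded windows would lower the share of peaks scored against the genome-wide background there. That share was lower on average, although no input reads were used. On the major arms its mean was 13.6 ± 21.0% (SD over 230 windows with 5 or more peaks) and 31.0 ± 43.3% (SD over 891 windows with 1 or 2). The difference was -17.5 percentage points (two-sided permutation p = 1e-05, the smallest possible). Among the peaks at or above the median score it was -11.8 (permutation p = 0.0626). This bears on the background in such windows and not on the cause of the crowding. Where MACS takes the larger background, a raised one lowers scores. The lower share does not hold throughout, since 8 of the 18 peaks in the chain on X at 1454968 to 1490464 and 5 of the 10 in the chain on 2R at 13676266 to 13699337 were scored against the genome-wide background. Whether the input was raised in the other crowded windows stays open, and no biological explanation could be tested without annotation.

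Another pattern is the higher score of peaks on X. If single X copies in males had left X below the genome-wide background, more X peaks would be scored against that background than autosomal ones. The difference between X and the autosome arms was -0.531 percentage points (18.9% against 19.4%), and its 95% bootstrap interval, -5.89 to 4.68, allows either direction. The share therefore does not decide whether X lay below that background, because the size of the predicted difference is not known. Fewer X copies would also lower the ChIP signal, while MACS does not let the background fall below the genome-wide rate. By themselves they would lower X scores, whereas the median score per 1 Mb bin was 2.88 higher on X. This direction argues against the explanation, although X peaks lost below the unknown threshold of the call cannot be counted. The sex of the larvae is not given, and no biological explanation was tested.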

How the results depend on the processing

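The grouping of peaks, the smaller gaps, the correlation of score with width and the excess of 2R over 2L kept their direction and their side of the threshold under each alternative run. The crowded windows stood at 3.05 to 27.8 times their number in random placements, the gaps at 0.527 to 0.671 of theirs, and the correlation at 0.559 to 0.759. Limiting the list to the peaks at or above the median score left 2195 peaks by construction. In that stricter list the shares of 2R, 3L and 3R fell to 19.5%, 17.6% and 21.4%, and those of X and chromosome 4 rose to 16.9% and 1.46%. In it, 3 comparisons no longer passed the threshold: the X difference in median score (2.69), the percentile of chromosome 4 (69.3) and the background share in crowded windows (a difference of -11.8 percentage points). The cause was not tested. The X and chromosome 4 comparisons are of the score on which that list was cut, which can by itself narrow them. Leaving out all sequence but the major arms moved the shares of 2R, 3L and 3R to 22.3%, 20.3% and 25.5%, because the total is smaller. The percent of scores on a Poisson tail was 25.8% with a tolerance of 0.01 and 18.1% in the stricter list. With the same tolerance the difference in background share was -16.4 percentage points for crowded minus sparse windows, 14.6 for other sequence minus the major arms and -0.309 for X minus the autosome arms. It raised the share on chromosome 4 from 5.0 to 10.0%. The comparisons through bins, the runs and the Poisson tails, with their alternatives, were chosen after seeing the data. No paired analysis was possible because the peak list keeps no library apart, and for the same reason no replicate could be left out. The planned tests on gene positions, gene lists and motifs, with their alternatives, were not run. Depth limits the weakest peaks first, but the depth of the libraries is unknown.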

Other observations

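Runs of close peaks were also counted without the grid of windows. On the arms 2L, 2R, 3L, 3R, X and 4, 9 chains of 10 or more peaks had no gap above 5 kb, and they held 115 peaks in all, whereas the 1000 random placements contained 0 such chains. The largest was on X at 1454968 to 1490464, with 18 peaks over 35.5 kb and a median score of 12.28. It was followed by 15 peaks on 3R at 12050187 to 12081083 (median score 21.44), 15 on X at 1497945 to 1521346 (14.08), 14 on 3L at 17550034 to 17572978 (19.69) and 12 on 3R at 13525414 to 13544146 (14.66). In the largest, 8 of the 18 peaks were scored against the genome-wide background, and in the other 4 of these chains 0 were, although 1 peak in each of the 2 on 3R missed a Poisson tail by 0.01. The remaining 4 were on 2R at 20426756 to 20441199 with 11 peaks, on 2L at 5286652 to 5307121 with 10, on 2R at 13676266 to 13699337 with 10 and on 2R at 18563592 to 18577390 with 10. In that order, 0, 0, 5 and 1 of their peaks were scored against the genome-wide background. In the 2L chain, 2 peaks missed a tail by 0.01. The 2 chains on X are separated by less than 10 kb. The chains on X, on 3L and on 3R at 12050187 to 12081083 consist of peaks in the 50 kb windows named above. They are therefore not separate support for the grouping. Of the 40 peaks on chromosome 4, 2 were scored against the genome-wide background (5.0%, exact 95% interval 0.611 to 16.9%), against 19.3% on the major arms. Counting scores that miss a tail by 0.01 makes this 4 of 40 (10.0%, exact 95% interval 2.79 to 23.7%), against 25.1% on the major arms, where chance gives 7.34% and 8.71%.

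The following was found after seeing the scores and is a hypothesis about their meaning. If the score is −log10 of a Poisson tail, the best background rate, 66.43, should place more scores on whole-count tails than rates well away from it. It placed 2.67 times as many as the best of the rates more than 0.1 away, while closer rates share many of its matches. Since MACS lets the background rise above this rate but not fall below it, and a given score needs a smaller fold at a higher background, each score then sets an upper limit on the fold of the pileup over background. The limit was 7.72-fold for the strongest peak (513 fragments over 66.43), 2.14-fold at the median and 1.64-fold for the weakest. At a background of 2 times the rate, the highest score would correspond to 5.30-fold. Under this reading at least 1530 peaks (34.9%) lie below 2-fold over the background that MACS used, and at most 245 above 4-fold. Where the input lies below the genome-wide rate, the fold over the input itself can exceed these limits. They also hold for the whole larva and not for the bound cells alone.

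Both tests in this paragraph were written down before their results were seen. The first asked whether peaks are fewer next to the centromeres, which lie at the high end of 2L, 3L and X and at the low end of 2R and 3R. The last, partial bin of each arm was left out, and on 2L, 3L and X it holds the sequence nearest the centromere. On these arms the tested bins therefore lie beside that partial bin, whereas on 2R and 3R they start at the low end. The 10 full bins of 1 Mb nearest the centromeres held 26.9 ± 16.7 peaks and the other 106 held 35.6 ± 13.4 (SD over bins). The difference was -8.68 peaks per Mb (two-sided permutation test within arms, p = 0.0462). The proximal bins held fewer peaks than the rest on 4 of the 5 arms. On 3R they held more, 49.5 against 36.2, and without 3R the difference was -14.1 (permutation p = 0.0059). Without 2L it was -10.4 (permutation p = 0.046). It no longer passed the threshold without X (-5.84, permutation p = 0.199), without 2R (-5.89, p = 0.215) or without 3L (-7.15, p = 0.146). The second asked whether strong peaks lie beside strong peaks. Over 4105 pairs of neighbours on the major arms the Spearman correlation of scores was 0.054 (permutation p = 5.4e-04), above 0 but small.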
